A study of Arabidopsis thaliana with 8 samples.

How the data were processed

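The series holds RNA-seq libraries from shoots of Arabidopsis thaliana seedlings aged 7 days, grown on vertical agar plates in cycles of 16 h of light and 8 h of dark, per the labels' protocols. The labels describe 8 libraries, 2 for each of 4 genotypes: Col (the Columbia accession, which serves as the reference genotype), the single genotypes CA1-1 and cae2-1, and the combination of both. Total RNA was extracted with a TRIzol-based method and libraries were made with Illumina chemistry, per the labels' protocols.

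The values used are raw read counts per gene model, as deposited and named so in the table's column headers, with no normalization by the authors recorded there. The genome build was TAIR10, per the submitters' processing notes. The aligner, the counting tool, the strand setting, the treatment of reads that match several genes and any filter on gene models are not given in the sources used here. Each gene model (a locus with an isoform number) has its own row, and 207 of 17710 loci have several models. How reads were divided among the models of a locus is not given either. Each column name also carries a number in brackets, with no stated meaning, that exceeds the sum of the column.

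Only columns whose names match a sample title were used. The 2 columns for Col, replicates 1 and 2, match. The titles of the other 6 samples match no column, so titles and column names follow schemes that differ in part. That these 2 columns are Col therefore rests on their names alone and was not checked from the values. The other 6 count columns bear letters that match no title or description of this series, so their genotype could be assigned only from column order or from the values themselves, and they were not used in any step. The contrasts planned before the data were examined (each single genotype and the combination against Col, the combination against each single genotype, the interaction, and the correlation of fold changes) therefore were not analysed here. The rule for naming genes from those contrasts fell with them. It was replaced, after the values were seen, by the 20 most abundant models (as a group), up to 3 of the abundant members of each gene list, ROP2, and the 8 models with the highest and the 8 with the lowest ratio between the Col replicates among those that differed beyond counting noise at a mean of at least 20 CPM. List members with low or null counts, and a few with large or small differences between the replicates, are named as well and were also chosen after their values were seen.

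The 2 libraries were scaled with edgeR 4.0.16 (R 4.3.3) by the trimmed mean of M values (TMM) over all listed models, and levels are CPM, the count relative to the scaled library size. Levels were not corrected for transcript length, so ranks between genes may also depend on length. Neither library lists a count of 1 for any model, so single counts appear to have been set to 0 before deposit, by a step that is not given. A listed 0 was therefore read as at most 1 count, which allows up to 4.74 counts (one-sided 95% Poisson limit), or 1.90 CPM in replicate 1 and 1.91 CPM in replicate 2. For each model with a mean of at least 5 CPM, an exact binomial test (two-sided, scipy 1.17.1) asked whether its counts split between the 2 libraries as the scaled library sizes do, with Benjamini-Hochberg adjustment and a threshold of 0.05. This test compares 2 libraries of one genotype against counting noise only. Reads without molecular identifiers are not independent molecules, so all intervals and limits cover counting error only. Log2 ratios were taken as replicate 1 over replicate 2 after adding 0.5 CPM to each. The spread between the libraries beyond counting noise was estimated as edgeR's common biological coefficient of variation. The labels call the replicates biological but do not say whether they came from separate plates or days.

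A set of 26 gene lists with 468 genes was fixed before the data were examined. Of these genes, 352 were listed in the table, and the most abundant model stood for its locus. Gene names came from the reference annotation of assembly TAIR10.1, matched by locus tag for 17825 of 17921 models. No coordinates are printed because that assembly is not the build named by the submitters. For each list with at least 5 members at a mean of 5 CPM or more, the median log2 ratio between the replicates was placed among 10000 random lists of the same size matched on mean CPM in 20 bins. Each member of a random list was drawn on its own from its bin, with replacement, so this resampling test treats genes as independent. GC content and transcript length were taken from the longest spliced transcript of the locus in the TAIR10.1 annotation.

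The steps were tested on simulated data. With counts drawn at the means of the 10701 models at 5 CPM or more, coefficients of variation set at 0.1 and 0.4 were recovered as 0.104 and 0.395. With counting noise only and 200 of these models changed 4-fold, the exact test called 99.5% of the changed models and 12 unchanged ones. Of 200 random lists of 10 genes, 6% had a p under 0.05. Alternatives to the scaling, the library size and the filter on low counts are given in the closing section.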

Results

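The series compared shoots of young Arabidopsis seedlings of 4 genotypes that differ in the shape of their cotyledon cells: Col, the single genotypes CA1-1 and cae2-1, and the combination of both, with 2 libraries each. Only the 2 Col columns of the count table carry names that match the sample labels. The data described are therefore taken, by name only, as those of Col, and the comparisons between genotypes were not analysed here. The listed gene models summed to 2571129 counts in replicate 1 and 2408685 in replicate 2, which is 55.5% and 53.6% of the numbers given in the column names. Of 17921 models, 13759 were listed above 0 in replicate 1 and 13805 in replicate 2, and 3435 were listed at 0 in both. No model was listed at a count of 1 in either library, while 690 in replicate 1 and 715 in replicate 2 were listed at 2, so a listed 0 can stand for 1. A mean of at least 5 CPM was reached by 10701 models, of at least 100 CPM by 1990 and of at least 1000 CPM by 108.

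Of the 26 gene lists, that of nuclear photosynthesis genes had the highest median in Col shoots, and its listed members summed to 80895 CPM in replicate 1 and 59136 CPM in replicate 2. Only 16 of the 26 genes fixed for this list were listed. RBCS1A, RBCS2B, RCA and LHCB2.1 were among those that were not, so ranks hold among listed models only. The most abundant listed model was PSBR (AT1G79040), a subunit of photosystem II, at 12965 ± 7288 CPM (SD, n = 2). It was followed by the light-harvesting gene LHCB1.3 (AT1G29930, CAB1) at 10688 ± 4757 CPM and by the metallothionein gene MT2A (AT3G09390) at 10158 ± 459 CPM. The photosystem I antenna gene LHCA2 (AT3G61470) stood at 7660 ± 3904 CPM, PSBO1 (AT5G66570), of the oxygen-evolving complex, at 7213 ± 2470 CPM, and the photosystem I subunit gene PSAD1 (AT4G02770) at 7165 ± 2833 CPM. Of 16 listed nuclear photosynthesis genes, 13 reached 100 CPM, and the list median was 4952 CPM in replicate 1 and 4064 CPM in replicate 2. The LHCB1 genes are similar copies, so the division of reads among them is uncertain, and LHCB1.1 was not listed. The 10 most abundant listed models took 9.83% of the listed counts in replicate 1 and 7.04% in replicate 2. Models of the chloroplast genome took 0.0825% of the counts in replicate 1 (95% Wilson interval 0.0790 to 0.0860) and 0.0993% in replicate 2 (0.0954 to 0.103). Models of the mitochondrial genome took 0.0475% (0.0449 to 0.0503) and 0.0651% (0.0620 to 0.0684).

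Genes of the epidermis and of wall growth differed by list in how many were abundant. Of all 17921 models, 10701 reached 5 CPM and 1990 reached 100 CPM, and no test compared these lists with other genes. Of 5 listed genes of epidermal identity, 4 reached 5 CPM. LTP1, a lipid transfer protein of the epidermis, stood at 1792 ± 299.7 CPM and PDF1, an outer cell layer gene, at 499 ± 235 CPM. Of 18 listed genes of cuticle and very long chain fatty acid synthesis, 14 reached 100 CPM, led by FDH at 737 ± 439 CPM, LTPG1 at 670 ± 28.9 CPM and CER10 at 622 ± 71.1 CPM. All 8 genes of primary wall cellulose synthesis were listed and 7 reached 100 CPM. Among them the endoglucanase gene KOR1 stood at 844 ± 98.4 CPM, and the cellulose synthase genes CESA1 and CESA3 at 425 ± 42.7 and 346 ± 185 CPM. Of 25 listed expansin and xyloglucan enzyme genes, 11 reached 100 CPM, with XTH4 highest at 1819 ± 1813 CPM and XTH24 next at 544 ± 211 CPM. In the pectin list 1 of 7 listed genes did so, the pectin methylesterase gene PME3 at 217 ± 81.6 CPM.

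Genes tied to cell shape in the epidermis covered a wide range. Of 22 listed ROP GTPases (small GTPases that polarize plant cells) and their partners, 12 reached 5 CPM and 2 reached 100 CPM. The list was fixed with 34 genes, and ROP1, ROP3, ROP4, ROP6 and ROP10 were among those not listed. ROP2 (AT1G20090) had 274 counts in replicate 1 and 409 in replicate 2, or 137 ± 38.6 CPM, and ROP11 stood at 117 ± 21.4 CPM. The activator gene SPK1 stood at 91.2 ± 10.4 CPM. The effector gene RIC4 had 16 and 6 counts, or 4.42 ± 2.83 CPM, and RIC1 was listed at 0 in both libraries, which allows up to 1.90 CPM of the listed model in replicate 1 and 1.91 CPM in replicate 2. Such low counts belong to the listed model and need not be the level of the gene, since some genes with general or photosynthetic roles were near 0 as well. The antenna gene LHCA3 and the ribosomal protein gene RPL5B, each listed with isoform 2, were at 0 in both libraries, and the actin gene ACT2 had 6 and 10. Of 29 listed actins, tubulins and cytoskeletal regulators, 22 reached 5 CPM. The tubulin genes TUA4 and TUB4 stood at 1409 ± 218 and 678 ± 234 CPM and the actin gene ACT7 at 503 ± 157 CPM. Tubulin and actin copies are similar in sequence, and their split is uncertain. Early auxin response genes were expressed broadly, with 23 of 25 listed members at 5 CPM or more. IAA2 stood at 1212 ± 563 CPM, IAA7 at 526 ± 274 CPM and IAA19 at 359 ± 139 CPM. Of 8 listed auxin transporter genes 6 reached 5 CPM, led by PIN3 at 501 ± 81.3 CPM. All 5 listed brassinosteroid genes lay between 5 and 100 CPM, with BAS1 at 58.2 ± 32.3 CPM.

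Of 20 listed genes of the stomatal lineage and guard cells, 14 reached 5 CPM and 2 reached 100 CPM. The guard cell potassium channel gene KAT1 stood at 135 ± 123 CPM and the guard cell differentiation gene FAMA at 64.9 ± 3.24 CPM. Of 9 listed trichome genes, 4 reached 5 CPM, and GL2 was highest at 299 ± 2.88 CPM. All 21 listed genes of the mitotic and S phase list were below 100 CPM, with CYCD3;1 highest at 81.4 ± 12.4 CPM. Among 16 listed regulators of meristems and leaf growth, 14 reached 5 CPM and the receptor gene CLV1 was highest at 83.8 ± 53.9 CPM. Of 6 listed vascular markers 4 reached 5 CPM, and they were led by XCP2, a xylem protease gene, at 131 ± 83.5 CPM, and by the phloem sucrose transporter gene SUC2 at 84.4 ± 42.8 CPM.

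Genes known from other organs had few counts, with the same limit on low counts of a listed model. Of 15 listed root markers, 9 were listed at 0 in both libraries and 2 reached 5 CPM, the endodermal genes CASP1 at 12.8 ± 11.9 CPM and CASP2 at 7.63 ± 1.12 CPM. Of 6 listed seed storage and late embryogenesis genes, 5 were listed at 0 in both libraries, and SESA1 stood at 1.81 ± 0.287 CPM. The salicylic acid and immune list was low as well, with 5 of 16 listed members at 5 CPM or more, 8 listed at 0 in both libraries, and NPR1 highest at 36.0 ± 3.76 CPM. Of 13 listed flavonoid genes, 2 reached 5 CPM, CHI at 69.7 ± 28.8 CPM and CHS at 25.7 ± 10.8 CPM. Of 9 listed heat shock and folding genes 3 did so, with the chaperone gene BIP1 at 118 ± 8.60 CPM. Other response genes were higher. Of 16 listed jasmonate genes, 12 reached 5 CPM, with the synthesis gene AOC2 at 728 ± 229 CPM. Of 14 listed genes of the abscisic acid, drought and cold list, 12 did so, with the cold-regulated gene COR47 at 744 ± 109 CPM. All 8 listed touch and wound genes and all 6 listed clock genes reached 5 CPM, with WRKY40 at 324 ± 247 CPM and TOC1 at 360 ± 84.5 CPM. Of 9 listed ribosome genes 7 reached 100 CPM, with the ribosomal protein gene RPL23AA at 619 ± 450 CPM.

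**Figure D1:**
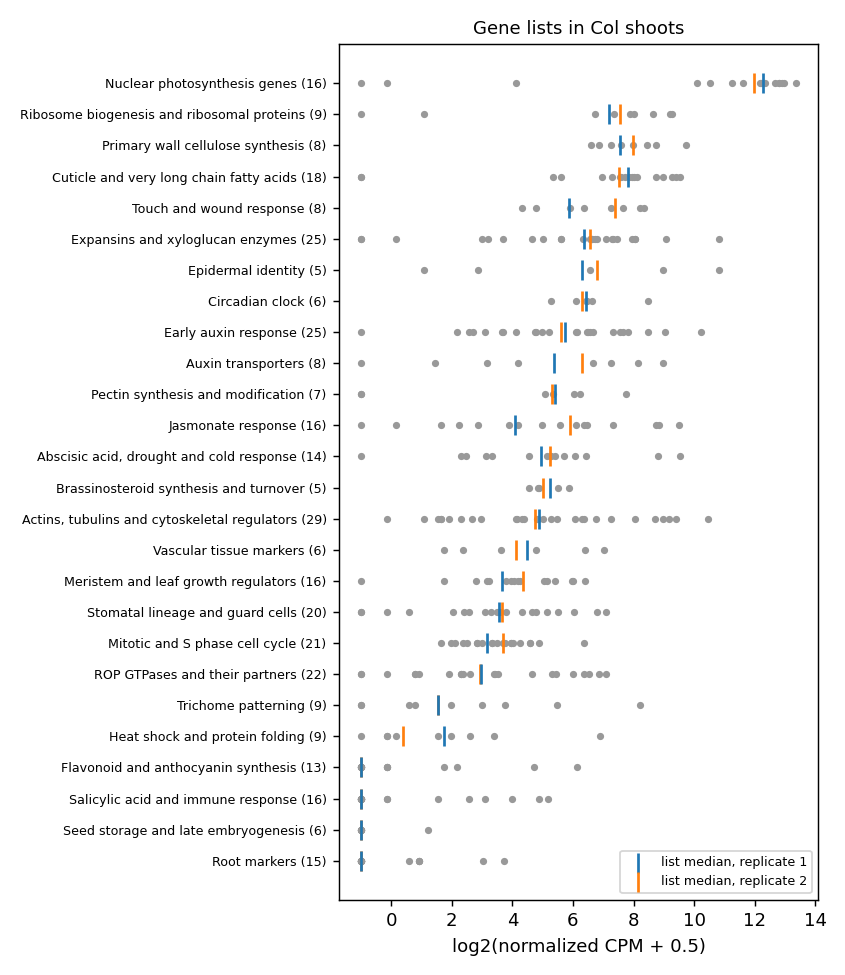
Levels of the 26 gene lists in Col shoots, as log2(normalized CPM + 0.5). Each grey point is the mean of 2 libraries for one listed gene, blue and orange bars are the list medians in replicates 1 and 2, and brackets give the number of listed genes. Nuclear photosynthesis genes had the highest medians, 4952 and 4064 CPM. The medians of root markers, seed genes, the salicylic acid and immune list and the flavonoid list were 0.

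The 2 Col libraries differed well beyond counting noise. Across the 10701 models at 5 CPM or more, which are not independent replicates, their levels had a Spearman correlation of 0.853 and a Pearson correlation of 0.865 on the log2 scale. The exact binomial test called 5835 models (54.5%), 2934 higher in replicate 1 and 2901 higher in replicate 2, and 2640 of the called models differed at least 2-fold. Without TMM scaling the calls split as 2572 higher in replicate 1 and 3215 higher in replicate 2. The biological coefficient of variation was 0.407. The SD of the log2 ratio was 0.89 for models at 20 to 50 CPM and 0.87 for models above 1000 CPM, where counting noise alone gave 0.23 and 0.03. They were counted as 2 samples.

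Named genes show the size of these differences. XTH4, a xyloglucan enzyme gene, had 3101 CPM in replicate 1 and 537 CPM in replicate 2. KAT1 had 222 and 47.9 CPM, and the leaf growth regulator TCP3 had 99.5 and 25.3 CPM. In the other direction, the transcription factor genes of rapid stress responses WRKY33 (44.5 and 261 CPM), ZAT10 (71.0 and 335 CPM) and WRKY40 (149 and 499 CPM) were higher in replicate 2. The wall gene TCH4, which is induced by touch, had 116 CPM in replicate 1 and 415 CPM in replicate 2. ERF104, another transcription factor gene of the touch and wound list, was higher in replicate 1 (114 and 48.7 CPM). Each of these genes passed the exact test, which compares these libraries and not conditions. FAMA, GL2 and LTPG1 did not pass it (adjusted p = 0.66, 0.88 and 0.13 by the exact binomial test).

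Single genes were tested against counting noise only, while lists were placed among random lists that carry the full gene-by-gene spread. Of 19 lists tested, 5 had a median log2 ratio outside the central 95% of random lists (unadjusted), where 0.95 would be so by chance, and 0 of 19 passed after Benjamini-Hochberg adjustment. The touch and wound list had a median of −0.84, with 7 of 8 members higher in replicate 2 (0.61st percentile of random lists). With only models at 20 CPM or more, its median was −0.74, at the 2.73rd percentile and so inside the central 95%. The mitotic and S phase list had a median of −0.70 with 10 of 17 higher in replicate 2 (0.51st percentile). The early auxin response list had a median of 0.59 with 15 of 23 members higher in replicate 1 (99.6th percentile). These 3 lists shared an adjusted p of 0.0785 by the random-list resampling test. The meristem and leaf growth list had a median of −0.60, with 9 of 14 members higher in replicate 2. That of the nuclear photosynthesis list was 0.59, with 11 of 14 higher in replicate 1. Both lists had an adjusted p of 0.154 by the same resampling test.

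**Figure D2:**
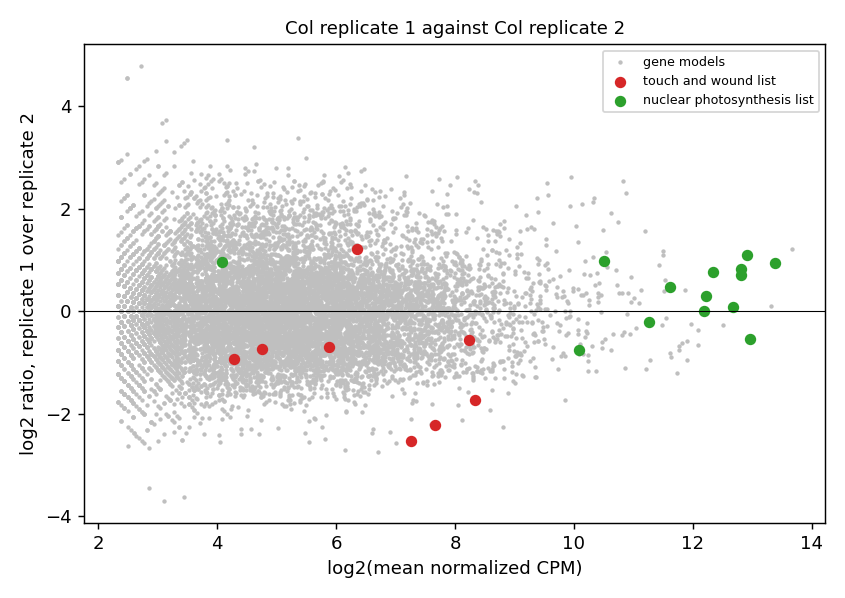
Log2 ratio of Col replicate 1 over replicate 2 against the log2 mean normalized CPM, for the 10701 gene models at 5 CPM or more. Grey points are models, red points the touch and wound list and green points the nuclear photosynthesis list; 7 of 8 red points lie below 0 and 11 of 14 green points above it.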

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

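All alternatives here were chosen after seeing the data. None of the contrasts between genotypes was run, so DESeq2, the replicate block and leaving out replicates were not run for them. No paired analysis was possible because the columns of the other genotypes could not be matched to samples, and Col alone has no pairs. The 6 alternatives were RLE factors, no scaling, organelle genes left out, the number in the column name as library size, and other filters on level. Those filters were a mean of at least 1 or 20 CPM. The RLE factors (relative log expression, the method of DESeq2 size factors) were computed in edgeR. The number of models beyond counting noise ranged from 4632 of 6994 tested (mean of at least 20 CPM) to 5961 of 13241 tested (at least 1 CPM). The number tested changes with the filter, so these counts do not rank the filters by share called. The number that also differed at least 2-fold ranged from 1616 to 2886. Its lowest value, 1616, came with a mean CPM of at least 20, where fewer models (6994) were tested. The coefficient of variation stayed between 0.396 and 0.412. The Spearman correlation ranged from 0.748 at 20 CPM or more to 0.906 at 1 CPM or more, so it depends on the range of levels kept. The median log2 ratio of the touch and wound list ranged from −0.92 to −0.74. At 20 CPM or more it stood at −0.74 and at the 2.73rd percentile of random lists, just inside their central range. Counting noise was largest at the low end but stayed below the observed spread there as well. It gave an SD of the log2 ratio of 0.40 at 5 to 20 CPM, against 1.01 observed, and 0.10 at 100 to 300 CPM, against 0.80 observed.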

Other observations

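The models with the largest ratios between the Col replicates were picked for their values, and no theme among them was tested. Among the 8 with the lowest log2 ratio, so higher in replicate 2, were WRKY33 (−2.54), RRTF1 (−2.51), a redox-responsive transcription factor gene, ATL2 (−2.70), a ubiquitin ligase gene of early elicitor responses, PUB23 (−2.39), another stress-induced ubiquitin ligase gene, NUDT4 (−2.75) and DOF1 (−2.55). The 8 with the highest ratio, so higher in replicate 1, included NRPE5 (2.88), a subunit of an RNA polymerase, EPC1 (2.79), a glycosyltransferase gene, UGT74F2 (2.79), a glucosyltransferase of salicylic acid, and AT1G50575 (3.37). Of 12 tested jasmonate genes, the exact test called 7 higher in replicate 2. It called 1, LOX2, higher in replicate 1 (log2 ratio 1.18). The list median of −0.50 lay inside the central range of random lists (4.57th percentile, adjusted p = 0.249 by the random-list resampling test).

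All tests below were chosen after the results were seen. The spread between the 2 Col libraries is wide at every level of expression, and 3 explanations were tested. Sampling of few molecules predicts a spread that falls with abundance, but the SD above 1000 CPM was 0.983 of that at 20 to 50 CPM, which argues against it. GC content and transcript length together took 0.587% of the variance of the log2 ratio over 6981 models at 20 CPM or more and 0.44% over 3690 models at 5 to 20 CPM, which argues against these as the cause. If gene programmes that moved together were the main source of the spread, co-regulated genes would stay close. Yet 45 models of cytosolic ribosomal proteins had an SD of 0.977, within the range 0.67 to 1.03 of 1000 random sets of matched abundance. The spread within these 45 models was not narrowed, but reads shared by similar genes could also widen it. A shift shared by all 45 models would leave the SD unchanged, so it cannot tell whether they moved together. The fixed ribosome list had a median log2 ratio of −0.69, with 5 of 7 tested genes higher in replicate 2 (2.97th percentile, inside the central range). The 45 models cover ribosomal proteins only, so they cannot decide on other programmes. Of 19 gene lists tested, 5 had medians outside the central range of random lists (unadjusted), and 0 passed after adjustment. Coordinated programmes therefore stay open as a part of the cause. Uneven amplification or capture of particular fragments, and the authors' counting of reads shared by several models, may add such gene-by-gene differences, but neither was tested, and no biological explanation is given by the design.

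A hypothesis is that the shoots of replicate 2 had begun a rapid touch or wound response at harvest, since 7 of 8 listed touch and wound genes were higher there. The other listed gene, ERF104, was higher in replicate 1 (log2 ratio 1.22). Of the 13 genes fixed for this list only these 8 were listed, and TCH2 and TCH3 were not among them. The data do not single this list out: the mitotic and S phase list and the early auxin response list lay at the 0.51st and 99.6th percentile, with the same adjusted p. The touch and wound median lay at the 0.61st percentile of random lists, but with 19 lists tested the adjusted p was 0.0785, so the gene-by-gene spread alone cannot be told apart from a shared response. After removal of GC content and transcript length the median over the 8 genes was −0.97, at the 0.2 percentile of random lists. Over the 7 genes at 20 CPM or more, it was −0.74 (2.73rd percentile, inside the central range) before and −0.86 (1.32nd percentile) after the removal. The shift did not shrink. This is not separate evidence, because the same genes and libraries were used. GC content and length took 0.45% of the variance at 5 CPM or more. Nor does the removal argue for a shared response. Time of harvest and handling are not in the labels used here and stay open.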
